A study of Mus musculus with 12 samples.

How the data were processed

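DNA of 12 liver samples from male C3H/HeN mice aged 74 weeks was profiled by reduced-representation bisulfite sequencing (RRBS). In RRBS, genomic DNA is cut with MspI, an enzyme whose CCGG site holds a CpG, and the short fragments are bisulfite converted, so that unmethylated cytosines read as thymine. The fragments over-represent CpG-rich sequence, and CpGs outside them are not measured. The mice were second-generation (F2) males of a control group (CC) or of an arsenite group (AA), whose F1 parents had been exposed to arsenite during gestation; the groups are called lines here. The tissue was labelled normal liver (N), non-tumor liver (Tn) or liver tumor (Tt). The 4 groups of this series were CCTn, AAN, AATn and AATt, with 3 samples each. The control groups CCN and CCTt, with 3 samples each, had been deposited earlier in another series, and their samples were not analysed here. They enter only through the authors' comparisons. The normal and tumor comparisons thus set arsenite samples against controls of an earlier deposit, while both groups of the non-tumor comparison belong to this series. The labels do not say whether the samples of a group came from separate mice. Labels of the AATn and AATt samples share the numbers 5, 9 and 13, but no source used here states that they come from the same mice.

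The data used here were the authors' deposited lists of differentially methylated regions, 1 list per tissue, each comparing the control line with the arsenite line. Trim Galore, Bismark, methylKit and bedtools 2.25.0 were used on build mm10, per the submitters' processing notes. The region caller, the coverage minimum, the significance threshold and the read depth are not given in the sources used here. Each entry of a list gives a region, its methylation difference in percentage points, its number of CpG sites, the number of those called differentially methylated (DMCs), and the transcription start site (TSS) and gene nearest to it. Each value therefore belongs to a whole comparison of 3 samples with 3, and no standard deviation or confidence interval of a methylation difference could be computed. Depth per sample and per site is unknown here, so no detection limit is given. In all 1711 regions the difference was at least 20 percentage points, with at least 3 CpG sites and at least 1 DMC. Smaller differences were therefore not seen here, and a gene that is missing from a list was not shown to be unmethylated or unaffected.

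The sign of the difference is not defined in the sources used here. A positive value was read as higher methylation in the arsenite line, which holds if the authors passed the arsenite samples to methylKit as the treatment group. If they did the reverse in every list, every direction in the text turns over. The shares of regions with higher methylation in the arsenite line would then be 69.2% in normal liver, 40.4% in non-tumor liver and 31.3% in tumors, higher would become lower in each contrast between lists, each odds ratio would become its reciprocal, and the p-values would stay. No source used here states that the lists share the same sign, and their difference columns carry different names. If the normal list alone were reversed, its positive share would be 69.2%, against 68.7% in tumors. The contrast of their directions would then not stand, and signs at shared regions would change too. All samples came from one inbred strain that differs from the reference strain, so a strain variant at a CpG shifts both groups of a comparison.

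Properties of the lists were checked. Region length equalled end minus start plus 1 in all 1711 regions, so coordinates were taken as 1-based. The listed TSS distance, negative upstream on the strand of the gene, equalled the distance recomputed from the coordinates within 1 bp in all 1711 regions. A region of 4 bp in the normal list holds 3 CpG sites, which needs 5 bp on a single strand, and 2 regions of the tumor list were too short in the same way. In these regions at least, the sites must have been counted on both DNA strands, so a region of 3 sites can hold fewer than 3 CpG pairs. RefSeq accessions had lost their separator and leading zeros. After these were restored, 1679 entries matched the RefSeq gene table of GRCm38.p6 by accession and 31 by symbol, and 1 did not match. The listed TSS lay within 1 kb of the start of the matched gene in 83.2% of the 1697 entries with gene coordinates. That table gives gene spans only, so regions are described as inside or outside a gene span, and exons, introns and UTRs were not told apart. One symbol of the tumor list had become a spreadsheet date number and was read from its accession as Marchf10.

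Regions were counted per list and direction, and shares carry exact 95% Clopper-Pearson intervals, which cover counting error only. Two-sided Fisher's exact tests compared the share of positive differences between the lists (3 pairs), between regions within 1 kb of a TSS and farther ones (3 lists), and between each fixed gene list and all other tumor regions (10 lists with at least 1 region), with Benjamini-Hochberg adjustment in each family. These tests run over regions, which are not independent replicates of the exposure: they describe the lists and do not measure variation between mice. Regions of 2 lists were called shared when they overlapped by at least 1 bp. These tests, the 11 gene lists and the naming rule were fixed before the data were examined; bins of TSS distance and CpG number were not. The rule named, per comparison, the 10 largest positive and 10 largest negative differences within 10 kb of a TSS (all regions where 20 or fewer lay that close), genes in more than 1 list, up to 4 members per gene list, and the 5 genes with the most regions, with ties kept. The gene lists held imprinted genes, liver tumor oncogenes and suppressors, AP-1 and immediate early genes, hepatocyte function genes, arsenic metabolism and oxidative stress genes, DNA methylation and chromatin regulators, Wnt pathway genes, immune cell markers, markers of stellate, endothelial and bile duct cells, developmental transcription factor families, and adhesion genes. Regions entered a gene list by the nearest gene and not by gene span, and a gene could be in more than 1 list. No enrichment of a gene list was tested, because the regions that could have been listed were not known here.

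Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The tests were tested on simulated data, as lists of the real sizes in which each region took its sign independently. A call rate near the threshold with equal shares was therefore built in. The rates use unadjusted p-values and do not cover regions that vary together or differences between mice. With equal shares, 4.5% of 1000 simulated normal and tumor pairs were called at p below 0.05, and 97.7% were called with a planted difference of 20 percentage points. The test by TSS distance called a planted difference of 20 points in 93.3% of simulated tumor lists, 25.2% of normal lists and 9.3% of non-tumor lists, so the last 2 had little power. With the share of signs in the real non-tumor list, no split of its 3 regions near a TSS could have been called. The alternatives were a difference of at least 20 or 25 points, at least 2 DMCs, at least 5 CpG sites, autosomes only, merging of regions of 1 direction within 1 kb, counting each gene once, TSS windows of 5 and 10 kb, and other definitions of overlap.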

Results

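The series asked whether DNA methylation in the liver differs between second-generation (F2) male mice of an arsenite line and of a control line, in normal liver, in non-tumor liver and in liver tumors. Each tissue was compared in 3 arsenite-line and 3 control-line samples, and the 12 samples of this series were 74 weeks old. The authors' deposited lists held 107 regions for normal liver, 57 for non-tumor liver and 1547 for tumors, 1711 in all. The labels do not say whether the samples of a group came from separate mice. The values are group differences in percentage points without per-sample values, so they carry no replicate error. Read depth is unknown here. A positive difference is read as higher methylation in the arsenite line in every list, a sign that no source used here defines.

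In normal liver, negative differences prevailed. The authors' deposited table listed 74 regions with a negative and 33 with a positive difference, a positive share of 30.8% (exact 95% interval 22.3% to 40.5%). The median difference was 22.1 points among positive and -22.0 points among negative regions. The regions had a median length of 97 bp and a median of 4 CpG sites, and 66.4% rested on 1 differentially methylated CpG (DMC). Of the 107 regions, 71 lay inside a gene span, 13 within 1 kb of a TSS and 39 within 10 kb.

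Among regions within 10 kb of a TSS, the largest positive differences in the authors' deposited table were at Rad23b (32.8 points, 9925 bp upstream), which encodes a nucleotide excision repair factor, and at the protocadherin gene Pcdha11 (25.7 points, 273 bp downstream of its TSS). Smaller positive values in that table were at the galactose metabolism gene Galt (21.4 points), the kininogen gene Kng2 (21.7 points) and the sphingosine-1-phosphate receptor gene S1pr4 (20.04 points). The other 5 of the 10 were 1600029I14Rik, Wdr81, Ankrd33, Lrrc61 and Tmem189, at 20.6 to 24.2 points. The largest negative differences were at Mir5046 (-30.3 points) and Csnk1e (-29.3 points over 10 CpG sites, 7 of them DMCs), the gene of a casein kinase of the circadian clock. They were followed by Zfp750 (-29.2 points, 2 bp from its TSS), Adamtsl2 (-28.7 points), Rusc1 (-26.8 points, across its TSS) and Vash1 (-26.3 points). Tbc1d1, BC006965, Gm44 and Slc15a3 completed the 10, at -25.9 to -24.1 points.

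Few members of the fixed gene lists appeared in normal liver. Of the imprinted genes, 1 region was listed, with a negative difference: that of Peg3, a paternally expressed gene (chromosome 7, 6729941 to 6730300, mm10; -24.0 points over 12 CpG sites, 5 of them DMCs, 119 bp downstream of its TSS). Both listed hepatocyte function genes were negative in the authors' deposited table, namely Arg1, the arginase of the urea cycle (-22.2 points, across its TSS), and the fatty acid synthase gene Fasn (-21.1 points, 13572 bp downstream of its TSS). Both listed immediate early genes were negative too, Dusp6, an ERK phosphatase gene (-23.5 points, 28713 bp upstream), and Fosl2, an AP-1 subunit gene (-21.9 points, 82771 bp upstream). The adhesion genes Pcdha11 and Itgb5 (22.8 points) were positive. A region listed under Hsbp1 lay inside the span of the cadherin gene Cdh13 and was negative (-23.6 points). By nearest gene, the other 7 lists had 0 regions, among them the markers of immune and of stellate, endothelial and bile duct cells. A region nearest to Ttc36 (-26.9 points) lay inside the span of the chromatin regulator gene Kmt2a and was not counted in that list.

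In non-tumor liver, the list was the shortest and had no clear majority. It held 34 positive and 23 negative regions, a positive share of 59.6% (exact 95% interval 45.8% to 72.4%). The median difference was 23.0 points among positive and -22.7 points among negative regions, and 52.6% of regions rested on 1 DMC. Within 10 kb of a TSS lay 17 regions, 11 of them positive.

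The positive regions near a TSS included Spry1, a feedback inhibitor of receptor tyrosine kinase signalling (24.2 points, 6 of 7 CpG sites DMCs, 2729 bp downstream of its TSS), in the authors' deposited table. Larger positive values stood at Sh3d21 and the homeobox gene Irx6 (27.6 points each), the integrin gene Itgb7 (27.1 points), Rtkn (25.8 points) and Coro1b (25.7 points). Rtkn had 2 DMCs among 4 sites, and the others had 1 DMC among 3 or 4 sites. The Sh3d21 and Itgb7 regions lay inside the spans of Thrap3 and Rarg, and that of Irx6 outside any gene span. Ankrd33, Ube2e1, 5830428M24Rik and Ccdc110 were also positive, at 20.04 to 24.9 points. A region across the listed TSS of the imprinted gene Igf2r, inside the overlapping transcript Airn, was positive (chromosome 17, 12769509 to 12769788; 20.4 points over 34 CpG sites, of which 3 were DMCs). The 6 negative regions in that table were at Thpo, the thrombopoietin gene (-21.0 points over 26 CpG sites, across its TSS), Hsd17b13, which encodes a hepatic lipid droplet enzyme (-21.2 points), Gas2l2 (-21.4 points), Aplp1 (-22.0 points), Armcx6 (-24.0 points) and G530011O06Rik (-24.5 points).

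Of the fixed lists, the developmental transcription factor families had 3 regions in non-tumor liver. In the authors' deposited table these were Irx6, Hoxd1 (21.6 points, 27116 bp from the TSS) and Foxl1 (-25.3 points, 135910 bp from the TSS). The imprinted list had Igf2r and, 448622 bp from its TSS, Cobl (-29.5 points). The Wnt list had Wnt16 (23.4 points, 81768 bp upstream and inside the span of Cped1), and the adhesion list had Itgb7 and Cdh15 (-21.6 points). By nearest gene, the other 7 lists had 0 regions.

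In tumors, the arsenite and control lines differed at far more listed regions, and positive differences prevailed. The authors' deposited table listed 1063 positive and 484 negative regions next to 1347 genes, a positive share of 68.7% (exact 95% interval 66.3% to 71.0%). The list was 14.5 times as long as that of normal liver and 27.1 times as long as that of non-tumor liver. The ratio to normal liver was 27.7 with at least 2 DMCs per region and 22.45 with a difference of at least 25 points. The differences reached 47.9 points among positive and -45.2 points among negative regions, with medians of 22.9 and -23.1 points. A single DMC supported 35.6% of the regions, and 695 lay outside any gene span.

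The largest positive differences within 10 kb of a TSS in the authors' deposited table were at BC048507 (42.3 points, 12 of 14 CpG sites DMCs, 357 bp downstream of its TSS) and the forkhead factor gene Foxi2 (chromosome 7, 135411842 to 135411960, inside the gene span; 40.7 points, 14 of 18 sites DMCs). Uqcc2 (37.4 points), the sodium channel gene Scn10a (34.9 points), the AMP deaminase gene Ampd3 (34.4 points) and Tnfrsf11a, the gene of the receptor RANK (32.9 points), were among the 10. The others were Hist1h2bc, Ap1g2, Tex11 and the chemokine receptor gene Cxcr1, at 32.4 to 33.0 points. The largest negative difference was inside Pik3c3, which encodes a lipid kinase needed for autophagy (chromosome 18, 30269424 to 30269487; -45.2 points, all 7 sites DMCs, 3409 bp upstream of the listed TSS). It was followed in that table by the chromatin remodeller gene Chd5 (-39.1 points), the peptide transporter gene Slc15a2 (-35.9 points), the serotonin receptor gene Htr2a (-35.1 points, all 4 sites DMCs), Nt5c2 (-34.6 points) and the paired box gene Pax8 (-33.1 points). The remaining members were Wnt3, Ict1, Cmtm8 and Epb4.1l3, at -33.0 to -31.6 points. Regions listed for Wnt3, Ict1, Nt5c2, Ap1g2 and Tex11 lay inside the spans of Wnt9b, Cdr2l, Ina, Jph4 and Gm9078, in that order.

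Several regions shared 1 nearest gene in some cases. By nearest TSS, Flt1, a VEGF receptor gene, and Cdh13, a cadherin gene, each had 4 regions, and all were positive in the authors' deposited table, at 21.0 to 28.4 points for Flt1 and 20.3 to 26.7 points for Cdh13. They lay inside the respective gene span, and the span of Cdh13 held 1 further positive region, listed under Hsbp1 (24.97 points). In normal liver, a region inside that span, also listed under Hsbp1, was negative (-23.6 points). Gpr133 had 4 positive tumor regions as well. The 4 positive regions whose nearest TSS was that of Taf4a lay inside the span of the cadherin gene Cdh4, more than 100 kb from that TSS. Ror2, a receptor for Wnt ligands, had 3 negative regions and 1 positive. 1700025C18Rik had 3 positive and 1 negative, and the positive ones 53952 and 66130 bp upstream lay inside the span of Cdh22. Erdr1, on the Y chromosome, had 2 of each. They lay 12700 to 2146047 bp from the listed TSS, so they are not a cluster at that gene.

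Among the fixed lists, the Wnt pathway genes had 12 tumor regions at 8 genes, of which 4 were positive and 8 negative. Of the 12, 3 lay within 10 kb of the TSS. The 2 Wnt3 regions were negative in the authors' deposited table, at -33.0 points (2992 bp upstream, inside the span of Wnt9b) and -23.3 points (inside Wnt3). That of the acyltransferase gene Porcn was negative (-24.1 points, 11027 bp upstream), and Rspo4 was positive (31.2 points, 31744 bp upstream). The receptor gene Fzd9 had 1 region of each sign (24.1 and -23.0 points, 17704 and 3290 bp upstream). The positive share of 33.3% differed from that of the other tumor regions at an unadjusted p of 0.0122 (Fisher's exact test, odds ratio 0.225) and not after adjustment over the 10 lists tested (adjusted p = 0.122). In none of the 10 lists did the direction split pass the adjusted threshold, and the Wnt list alone was below an unadjusted p of 0.05. The developmental transcription factor families had the most regions, 32 positive and 14 negative, against 1063 and 484 in the whole list (Fisher's exact test, adjusted p = 1.0). Foxi2, Pax2 (29.7 points, 58402 bp upstream) and Lhx4 (29.0 points) were positive in the authors' deposited table, and Pax8 was negative at 2 regions. Of these 46 regions, 6 were listed for transcripts that overlap or lie antisense to a factor gene, such as Sox2ot. Adhesion genes had 15 positive and 5 negative regions (Fisher's exact test, adjusted p = 0.978), and 2 of these 20 regions lay within 10 kb of the TSS. The authors' deposited table gave Cntnap4 at 35.3 points, Cdh20 at -29.7 points and Pcdh17 at 24.3 and 21.1 points. These regions lay outside the span of the listed gene, at 237742, 495180, 584216 and 372125 bp from the TSS, in that order.

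The lists that name liver tumor and cell type genes were short and split in direction. The list of oncogenes and suppressors included Tmem54, whose place there was fixed beforehand and is no finding about its role. Tmem54 had a negative region across its TSS in the authors' deposited table (chromosome 4, 129105356 to 129106478, -29.6 points, 38 of 52 sites DMCs). Mycn was negative (-25.7 points, 260835 bp away). Both Runx3 regions were positive (20.5 points, 50643 bp upstream, and 21.3 points, inside its span). The immune cell markers had 4 positive and 3 negative regions (Fisher's exact test, adjusted p = 0.978). Runx3 is in this list too, so both of its regions count again among the positive ones. Ptprc, which encodes the pan-leukocyte antigen CD45 (-33.0 points), and Cd74, the invariant chain gene of antigen-presenting cells (-23.7 points, 886 bp downstream of its TSS), were negative in the authors' deposited table, as was Zap70, a T cell kinase gene (-21.9 points), while Cd8a was positive (22.1 points). Of the stellate, endothelial and bile duct markers, Kdr (25.3 points) and Gpr182 (22.9 points) were positive. Gata4 (-21.2 points) and Cdh5 (-21.6 points, 10075 bp upstream) were negative. The Kdr region lay outside its gene span, 142664 bp from the TSS. The imprinted list had Rasgrf1 (23.1 points), Snurf (22.3 points, inside the span of Snrpn) and Sfmbt2 (21.6 points, 69266 bp upstream) on the positive side. Dlk1 (-24.1 points) was on the negative side. AP-1 and immediate early genes included Dusp6 with 1 positive (42.1 points, 58831 bp upstream) and 1 negative region (-21.0 points, 16900 bp downstream). Batf (27.0 points, 1714 bp upstream) and Atf3 (22.6 points, 33106 bp upstream) were positive. The chromatin regulators Ezh1 (-20.5 points) and Smarca2 (-20.8 points, 440033 bp upstream) were negative in that table. So was the lipogenic factor gene Srebf1 (-20.9 points, 9344 bp upstream and inside the span of Tom1l2). By nearest gene, the arsenic metabolism and oxidative stress list had 0 regions in every tissue.

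**Figure D1:**
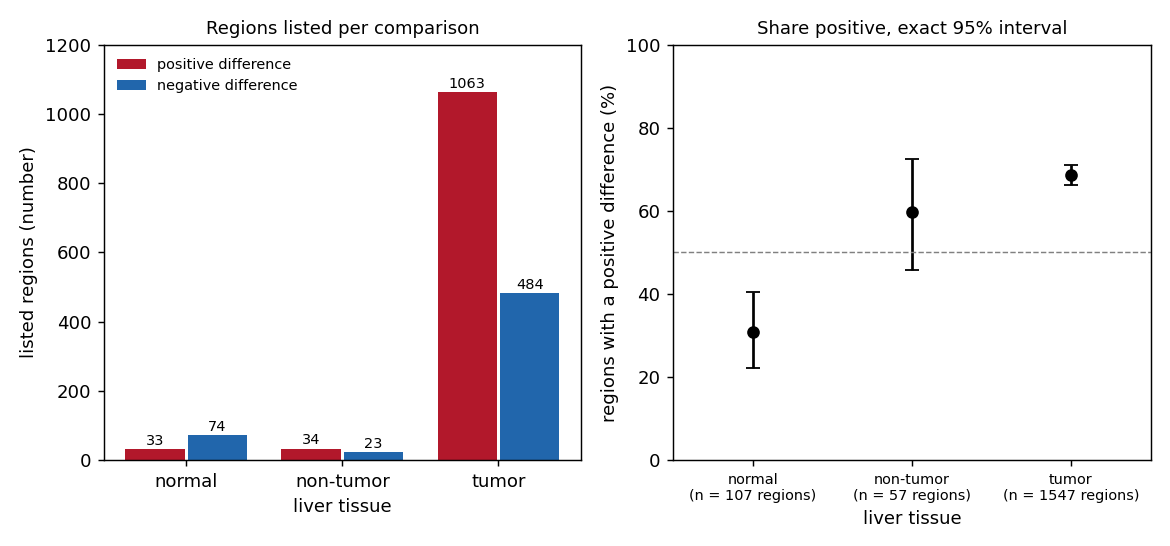
Left, number of listed regions (vertical axis) with a positive and a negative methylation difference in each liver tissue (horizontal axis). Right, share of positive differences in percent with its exact 95% interval over regions; normal liver lies at 30.8%, non-tumor liver at 59.6% and tumors at 68.7%.

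The majority direction was compared between the tissues over regions, with the sign of the difference taken as the same in every list. The positive share of 30.8% in normal liver was lower than the 68.7% in tumors (Fisher's exact test, odds ratio 0.203, adjusted p = 5.08e-14) and lower than the 59.6% in non-tumor liver (odds ratio 0.302, adjusted p = 6.79e-04). In Fisher's exact test, the second contrast was not past the threshold with at least 2 DMCs per region (adjusted p = 0.0582) or a difference of at least 25 points (adjusted p = 0.263), with a range of 6.60e-04 to 0.263 over its alternatives. Non-tumor liver and tumors were not distinguished (Fisher's exact test, odds ratio 0.673, adjusted p = 0.150).

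Tumor regions close to a TSS were positive less often than distant ones. Of the 72 regions within 1 kb of a TSS, 36 were positive (50%, exact 95% interval 37.98% to 62.02%), against 69.6% of the 1475 farther ones (67.2% to 72.0%; Fisher's exact test, odds ratio 0.436, adjusted p = 0.00294). The negative regions near a TSS included those at Tmem54, Htr2a and Cd74, and the positive ones BC048507 and Gpr182. Among the 368 regions more than 100 kb from a TSS, a bin chosen after seeing the data, 80.4% were positive (76.0% to 84.4%). In Fisher's exact test, the same contrast was not called in normal liver (13 regions within 1 kb; odds ratio 0.640, adjusted p = 1.0), where it had little power. In non-tumor liver (3 regions; odds ratio 1.38, Fisher's exact test, adjusted p = 1.0) it could not have been called, whatever the signs of the 3 regions. With a difference of at least 25 points, the tumor contrast had an odds ratio of 0.443 and was not called (Fisher's exact test, adjusted p = 0.191; 4.29e-05 to 0.191 over its alternatives).

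**Figure D2:**
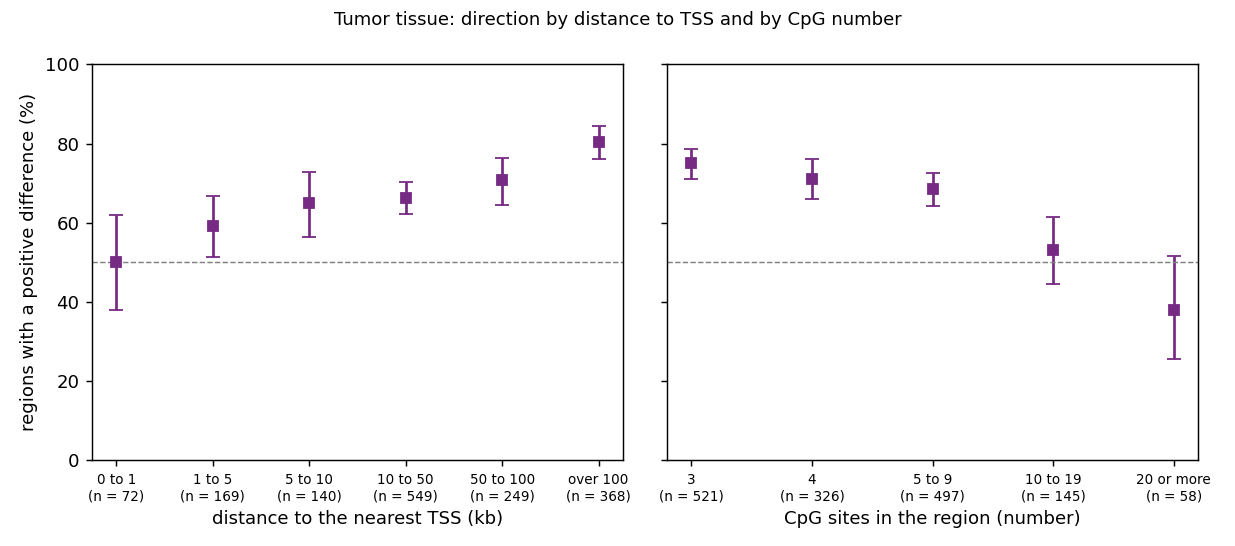
Share of tumor regions with a positive methylation difference in percent (vertical axis, squares, with exact 95% intervals over regions) by distance to the nearest TSS in kb (left) and by number of CpG sites in the region (right). The share runs from 50% within 1 kb to 80.4% beyond 100 kb, and from 75.05% at 3 CpG sites to 37.9% at 20 or more.

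Few positions were listed in more than 1 tissue. Whether their number exceeds that of random overlap was not tested, because the regions that could have been listed were not known here. Normal liver and tumors shared 11 regions, 5 with the same sign; normal and non-tumor liver shared 3, of which 2 had the same sign; and non-tumor liver and tumors shared 4, of which 3 had the same sign. Of these, only the region near Dact2, a Wnt signalling regulator gene, was in all 3 of the authors' deposited tables (chromosome 17, from 14094720, 109015 bp from the TSS in the normal and tumor tables). It lay outside any gene span and stood at -24.8 points in normal liver, 21.1 points in non-tumor liver and 29.2 points in tumors. A region inside Htr2a was negative in normal liver (-22.4 points) and tumors (-35.1 points), and one across the TSS of Ccdc110 was positive in non-tumor liver (20.04 points) and tumors (25.9 points). The region near Gm15446 was positive in non-tumor liver (21.2 points) and negative in tumors (-44.4 points). By nearest gene, 37 genes were named in more than 1 list. Normal liver and tumors shared 23 of them, 10 with a single sign over all regions, and non-tumor liver and tumors shared 13, 8 of them with a single sign.

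**Figure D3:**
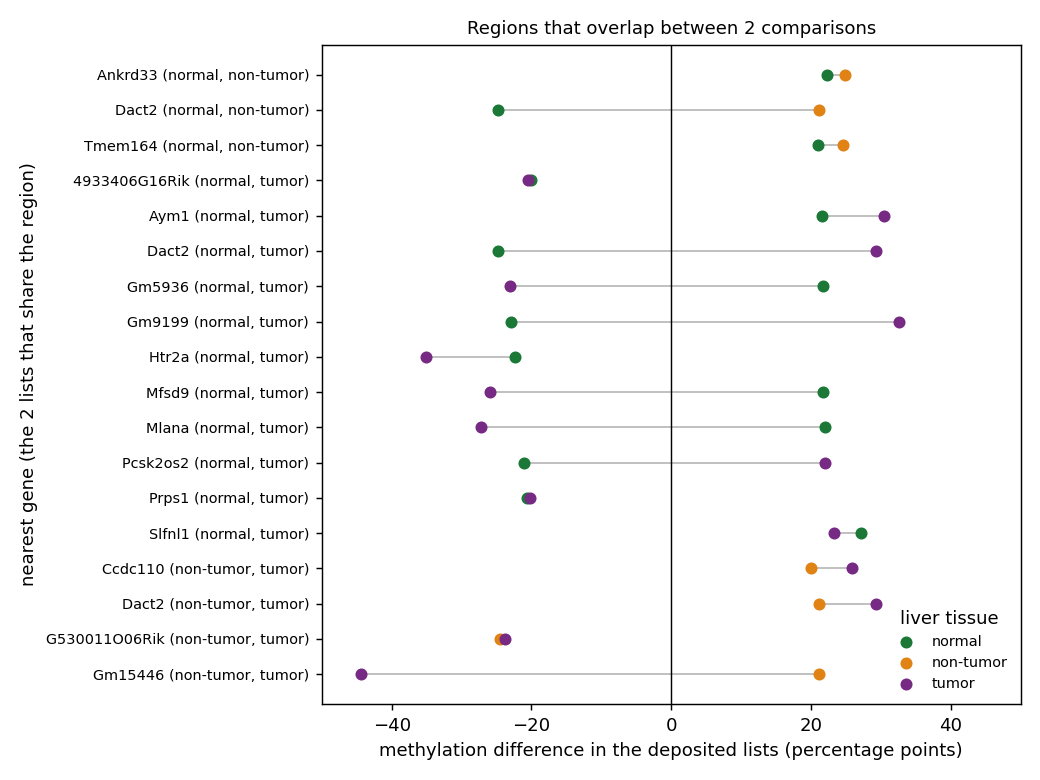
Methylation difference in percentage points (horizontal axis) of each region that overlaps between 2 of the deposited lists, by nearest gene (vertical axis), with points coloured by tissue and joined by a line. Of the 18 overlaps, 10 have the same sign in both lists and 8 have opposite signs, among them 2 of the 3 Dact2 pairs.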

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

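The tests of direction between tissues, of autosomes and of single tumors were set before their results were seen; those of a deposit offset, of DMC number and of CpG number were chosen after. All run over regions of the deposited lists, since no test over mice was possible here.

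The share of positive differences differed between tissues under the same contrast of arsenite line with control line: it was 30.8% in normal liver, against 68.7% in tumors (Fisher's exact test, adjusted p = 5.08e-14) and 59.6% in non-tumor liver (adjusted p = 6.79e-04). The controls of normal liver and tumors were deposited earlier than the arsenite samples, and an offset between the deposits stays open: the upper limit in normal liver, 40.5%, and the lower limit in tumors, 66.3%, lie on opposite sides of 50%, but 10.3% of the normal regions were listed in tumors too, so its sign may differ between the regions listed. Regions on the sex chromosomes, 5 of 107 in normal liver and 85 of 1547 in tumors, were too few to account for the contrast of normal liver with tumors, whatever their signs. Their number thus fixed that it was called on autosomes (Fisher's exact test, odds ratio 0.197, adjusted p = 5.74e-14). The contrast with non-tumor liver was called there as well (Fisher's exact test, odds ratio 0.282, adjusted p = 6.60e-04). The CpG number of the regions did not account for the contrast of normal liver with tumors either. With the tumor regions weighted to the CpG numbers of the normal list, their positive share was 71.4% (95% bootstrap interval over regions 69.0% to 73.8%, 10000 draws). This lay above the upper limit of 40.5% in normal liver. It follows from the tumor bins below 10 sites, each 68.6% to 75.05% positive, since only 3 normal regions had 10 or more sites. A sign set the other way in the normal list alone also stays open, and it would remove the contrast with tumors. Differences between single mice and a response to the exposure that differs between tissues stay open and were not tested, nor were other explanations of the contrast with non-tumor liver.

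The tumor list was far longer than the others, with 1547 regions against 107 and 57. The tumor list was 14.5 times as long as that of normal liver, which has the same split of deposits, but with depth unknown this ratio does not decide whether an offset between the deposits plays a part. Regions resting on 1 DMC did not account for the excess, since with at least 2 DMCs the tumor list was 27.7 times as long as that of normal liver and 36.9 times as long as that of non-tumor liver. Differences between single tumors with 3 samples per group could not be examined, because the lists used here hold 0 columns of per-sample methylation. That explanation, a difference in depth between tissues, an offset between the deposits and a tissue-specific effect of the exposure stay open.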

How the results depend on the processing

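The limits of at least 25 points, 2 DMCs and 5 CpG sites were chosen after seeing the data. The planned limit of 20 points removed no region and tested nothing, and merging and counting each gene once left the normal and non-tumor lists as they were. Without the 26 values that such settings could not change, 67 of 103 alternative values kept their direction and side of the threshold or, for counts, stayed within 1.5 times. A difference of at least 25 points left 20 regions in normal liver, 16 in non-tumor liver and 449 in tumors, at least 2 DMCs left 36, 27 and 997, and at least 5 CpG sites left 35, 19 and 700. The last limit lowered the positive share in tumors to 62.9%, since it left out the regions of 3 and 4 CpG sites, of which 75.05% and 71.2% were positive. The contrast of directions between normal and non-tumor liver lost its call at 25 points (odds ratio 0.333) and at 2 DMCs (odds ratio 0.3025), where fewer regions were tested. The contrast of non-tumor liver with tumors, not called as listed, turned to an odds ratio of 1.01 with at least 5 CpG sites, and that of TSS distance in normal liver, also not called, to 1.20 at 25 points. The TSS contrast in tumors lost its call at 25 points (odds ratio 0.443), where 449 regions were left. In non-tumor liver the TSS contrast gave no value at 25 points. The contrast of normal liver with tumors was called under its other 6 alternatives (Fisher's exact test, adjusted p from 5.12e-14 to 0.00274), and 0 gene lists were called under any alternative run. Requiring overlap of 50% of both regions left 1 region shared by normal and non-tumor liver, 0 with the same sign. It left 7 shared by normal liver and tumors, 2 with the same sign. Non-tumor liver and tumors kept 4, of which 3 had the same sign. At 25 points 0 regions were shared by any pair of lists. At least 2 DMCs left 1 region shared by normal and non-tumor liver and 3 by normal liver and tumors, with 0 and 1 of the same sign. At least 5 CpG sites left 1 and 2, again with 0 and 1 of the same sign. Shared genes of normal and non-tumor liver, of normal liver and tumors, and of non-tumor liver and tumors numbered 1, 3 and 3 within 10 kb of a TSS, 0, 1 and 2 at 25 points, 1, 9 and 6 with at least 2 DMCs, and 1, 4 and 4 with at least 5 CpG sites; each of these settings keeps fewer regions. The planned stricter limit on q was not run, because q values were not used here. Depth is unknown, so what it limits could not be examined. Leaving out single samples was not possible without per-sample values. No paired analysis was possible because the values belong to whole comparisons and carry no sample numbers.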

Other observations

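The tests of TSS distance among CpG-poor regions and of CpG number among distant regions were set before their results were seen; the split by CpG number, the test of shared positions and the test of chromosomes were chosen after.

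The 10 tumor regions with the most CpG sites, ranked after the values were seen, held 5 positive and 5 negative differences. In the authors' deposited table, regions inside Agap3 (22.8 points, 68 of 185 sites DMCs), Ildr2 (24.0 points, 48 of 128) and the opioid receptor gene Oprd1 (26.5 points, 43 of 75) were positive. So were regions across the TSS of Zfp263 (24.8 points, 50 of 77) and of Rsph3b (21.5 points, 25 of 57). On the negative side of that table were a region upstream of Atcayos and inside the kinase gene Dapk3 (-25.5 points, 65 of 135), one inside the homeobox gene Mkx (-25.8 points, 49 of 98) and one nearest to Nans and inside Trim14 (-20.1 points, 22 of 89). Colec12 (-20.2 points, 24 of 79) and Tmem54 (-29.6 points, 38 of 52) were negative across their TSS.

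Direction in tumors varied with both the CpG number and the TSS distance of a region. Of the 203 regions with at least 10 CpG sites, 48.8% were positive (exact 95% interval 41.7% to 55.9%), against 71.7% of the 1344 others (69.2% to 74.1%; Fisher's exact test, p = 2.25e-10). Among regions of fewer than 10 CpG sites, those within 1 kb still had an odds ratio of 0.511 (Fisher's exact test, unadjusted p = 0.0242). This single cut cannot decide whether CpG number accounts for the TSS contrast. Below it, the positive share still fell from 75.05% at 3 sites to 68.6% at 5 to 9. Among regions farther than 1 kb, the odds ratio of the CpG contrast was 0.392 (Fisher's exact test, unadjusted p = 1.19e-08). Closeness within 1 kb thus did not account for the whole CpG contrast, but distance beyond 1 kb was not held fixed. The regions that could have been listed were not known here, so the shares compare directions among listed regions and not how often a kind of region changed.

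A hypothesis that 1 exposure effect is carried in both normal liver and tumors predicts the same sign at shared positions. Of the 11 shared regions 5 had the same sign, 45.5% against 42.8% predicted from the shares of the lists (one-sided exact binomial test, p = 0.545; exact 95% interval 16.7% to 76.6%). The number was too small to decide. The opposite pairs near Gm5936 and near Dact2 had the same bounds in both of the authors' deposited tables, at 21.7 points in normal liver and -23.1 points in tumors for Gm5936, and at -24.8 and 29.2 points for Dact2.

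A hypothesis of a single split for all chromosomes was tested in the tumor list by permuting the signs. The positive share varied more between chromosomes than that split gave (chi-square statistic 36.2, 10000 permutations, p = 0.0150). Chromosome 17 had 32 positive and 33 negative regions, and chromosome 2 had 101 and 27. Regions lie in clusters, which the permutation does not take into account.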
